A study of Mus musculus with 24 samples.

How the data were processed

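RNA of spermatocytes and round spermatids from adult testes of WT and Nutm1 KO mice was measured on Illumina bead arrays with 45281 probes. Per the labels, cells were separated by sedimentation in a gradient of bovine serum albumin, 3 times per genotype, with 2 WT or 3 KO mice each time. Replicates 1 to 3 of each of the 4 groups are these fractionations, and replicates 4 to 6 are mixtures of replicates 1 and 2, 2 and 3, and 1 and 3. Same-numbered arrays of the stages of a genotype come from the same fractionation. Across genes, residuals of same-numbered arrays of the stages correlated at -0.23 to 0.46 (median 0.27), and those of other numbers at -0.52 to 0.28, while same numbers of KO and WT gave -0.30 to 0.09. Same numbers thus pair the stages within a genotype, by the labels, but not KO with WT. The fits carry no block, a choice made before the data were examined, and blocks were tried as alternatives.

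The deposited non-normalized table holds an intensity per probe and array, per the file headers, and its columns differ in median, so no normalization between arrays is evident. The scanner software, the summarization of beads and any background subtraction are not stated. The deposited detection p-value of each probe and array, per the file headers, runs from 0 to 1, and it is inferred, not stated, that it was computed against the negative control beads of each array. The intensity values that the authors deposited as processed are quantile-normalized on a linear scale. They keep the rank order of the non-normalized columns (lowest rank correlation 1.00), differ from a quantile normalization of these by a median of 9.41e-05 on the log2 scale, have array medians of 140.2 to 140.4 and reach down to 105.4. Mixed arrays had a median signal of 128 to 136 and 13507 to 16640 detected probes. Which slide an array was on is not given.

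Intensities of all 24 arrays were background-corrected with the detection p-values and quantile-normalized on the log2 scale (neqc of limma 3.58.1, offset 16, R 4.3.3). Probes with a detection p under 0.01 on at least 3 of the 12 direct arrays were kept (17401, 38.4%). Of all probes 34885 are listed with 1 gene (77.0%), 18 with several and 10378 with none. For 34807 the gene identifier was found in the RefSeq annotation of the mouse, which gave the current symbol and the chromosome. Each gene is given by its probe of highest mean, and unnamed probes were tested on their own, which made 12705 features (10076 named genes and 2629 unnamed probes). These are called genes in the counts.

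A linear model with the 4 groups was fitted to the 12 direct arrays, with moderated tests (limma lmFit and eBayes, residual degrees of freedom 8, prior 4.07). The contrasts were KO minus WT within each stage, the difference between these, and round spermatids minus spermatocytes within each genotype. Genes changed when the Benjamini-Hochberg adjusted p was under 0.05, and every adjusted p of a gene comes from this limma model. Where no direct array of the lower group detected a gene, the fold is given as "at least": the mean of the higher group against the lowest detected level on each array of the lower group, or the value itself if higher. Mean signals of lists and genes are on the neqc log2 scale.

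The genes named were set by a rule before the data were examined: Nutm1, the 10 largest rises and falls of each KO against WT comparison (5 for each stage comparison) among genes that passed, whose arrays lay apart and which were detected on all 3 arrays of the higher group, and the 5 smallest adjusted p of the difference between stages. Clone and locus names were passed over. From 29 gene lists fixed before the data were examined, members with the smallest p were named. The lists have 710 entries, of which 638 are on the array and 497 were measured. Sertoli cell and Leydig cell lists and the like serve as markers of other cells. Some genes are in more than 1 list. The set test is camera of limma with a preset correlation of 0.01, repeated with a correlation estimated from the data, and it compares a list with the other genes. With the estimated correlation it called 0 of the 29 lists in every comparison. A call lost there thus does not tell a weak list from a strong one, and the calls given rest on the preset correlation. Fry of limma asks whether the genes of a list move, on balance, in one direction, or, in its mixed form, in either, and compares with no other genes. Set test p values were adjusted over the 29 lists. "Over the list alone" means adjusted over the members of that list. Frequencies of X-linked genes were compared by 2-sided Fisher's exact tests.

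The model was tested on simulated data with the spread of these arrays. In a single simulation per stage 200 of 12705 genes were changed, with noise independent between genes. In round spermatids it recovered 1.61% of genes changed by log2 0.50, 38.6% of those changed by 1 and 97.1% of those changed by 2, and 2.08% of its calls were false. In spermatocytes it recovered 0%, 35% and 94.0%, and 4.55% of its calls were false. More genes passed in the real round spermatid data, which makes the adjusted threshold less strict, so these shares do not carry over to them. Correlations with the stage difference were compared with those of other splits of the same arrays, and the correlation of the effects in both stages with that of other splits of the fractionations, each taken with both of its stages. The differences of list means were recomputed without each array. These tests and the counts at bounds were chosen after the result was seen. Alternatives comprised other normalizations, the authors' values, other filters, every probe on its own, use of the mixed arrays, blocks, other variance models and leaving out each array. Protein, histone acetylation and the altered part of Nutm1 are not in these files, and the mixed arrays were left out of the comparisons because they hold no new animals.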

Results

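Gene expression was measured on bead arrays in germ cells of adult mice of a mixed B6 and 129 background, wild type (WT) or labelled as Nutm1 knockout (KO). Nutm1 encodes Nut, a testis protein known to bind the acetyltransferase p300. The array labels call the mutant a KO, whereas the design text calls it a knock down. Spermatocytes (meiotic cells) and round spermatids (haploid cells that follow meiosis) were separated by sedimentation through a gradient of bovine serum albumin. Each of the 4 groups has 6 arrays. Replicates 1 to 3 come from separate fractionations of 2 WT or 3 KO mice each, and replicates 4 to 6 are mixtures of their RNA, so the comparisons rest on the 3 direct arrays per group. The direct arrays had a median signal of 136 to 171 and detected 13849 to 16244 of 45281 probes. Detected probes averaged 15697 ± 151 (SD, n = 3) in KO round spermatids and 14444 ± 735 in WT round spermatids. They averaged 15232 ± 920 in KO spermatocytes and 15767 ± 375 in WT spermatocytes.

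Nutm1 RNA was lower in KO round spermatids but was still detected on all 3 of their arrays. Its signal (log2) was 6.86 ± 0.15 (SD, n = 3) in KO and 8.37 ± 0.17 in WT round spermatids, a difference of -1.50 (SE 0.24, adjusted p = 0.00156). The KO arrays read 6.81, 6.75 and 7.03, and the WT arrays read 8.52, 8.40 and 8.18. In spermatocytes the signal was 5.63 ± 0.10 in KO and 6.27 ± 0.57 in WT, a difference of -0.65 (SE 0.24) that did not pass (adjusted p = 0.546). There the KO arrays read 5.51, 5.69 and 5.67, of which 2 were detected, and the WT arrays read 5.76, 6.17 and 6.89. The test of the difference between the stages did not pass either (-0.86, SE 0.35, adjusted p = 0.275). A single probe reads Nutm1, and the files do not give the altered part of the gene, so a probe outside that part would check nothing.

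**Figure D1:**
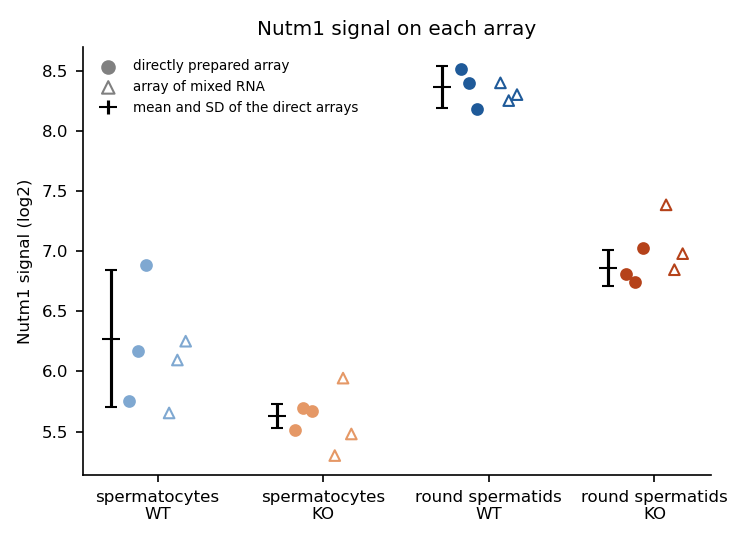
Nutm1 signal (log2, vertical axis) on each array of the 4 groups (horizontal axis), with filled circles for direct arrays, open triangles for arrays of mixed RNA, and bars for the mean and SD of the 3 direct arrays. The direct KO round spermatid arrays lie between 6.75 and 7.03, below the WT arrays at 8.18 to 8.52.

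The comparison of KO with WT round spermatids asks which transcripts change in the haploid cells that follow meiosis. The largest fitted changes were falls. Bpifa3, of the family of bactericidal/permeability-increasing proteins, fell by 7.68 on the log2 scale (SE 0.42, adjusted p = 4.21e-07). Car2, a carbonic anhydrase, fell by 6.67 (SE 0.40), and the differences of Dydc2 and the cytochrome P450 gene Cyp2a12 were -6.58 (SE 0.24) and -6.61 (SE 0.26). The falls of Bpifa3 and Cyp2a12 are at least 131-fold and at least 51.3-fold, because no KO round spermatid array detected these genes. The largest fitted rises were of B4galt5, a galactosyltransferase (3.23, SE 0.24, at least 6.18-fold), the tetraspanin gene Tspan17 (3.02, SE 0.24, 8.13-fold) and Cnga3, a subunit of a cyclic nucleotide-gated channel (2.82, SE 0.34). Here and below the order is that of fitted differences, so a gene known only by its bound, such as B4galt5, can precede one with a larger measured fold, such as Tspan17.

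Of 12705 genes and unnamed probes tested, 1890 changed in round spermatids, 875 higher and 1015 lower in KO (745 and 715 with a gene symbol). Large falls outnumbered large rises. A fitted change of at least 2-fold was seen in 763 falls and 242 rises, and one of at least 8-fold in 98 falls and 4 rises. With the 185 falls and 110 rises not detected on any array of the lower group taken at their bounds, these counts are 709 and 212, and 76 and 3. The other 6 of the 10 largest falls were Tmod4 (-5.92, at least 36.9-fold), a tropomodulin, Glt6d1 (-5.68), the cystatin-like gene Cstl1 (-5.61), Odf3b (-5.09) and the kallikrein genes Klk1b9 (-5.75, at least 33.7-fold) and Klk1b26 (-5.50). The Klk1b paralogs are alike in sequence, so which of them a probe reads is uncertain. The other 7 of the 10 largest rises were Lrrc3 (2.67, at least 3.76-fold), Paqr3 (2.47), the transcription factor gene Elk4 (2.37, at least 2.42-fold), C1qtnf12 (2.30), Cmtm4 (2.26), the RNA-binding protein gene Rbm45 (2.23) and Mtmr3 (2.05). All 20 of these genes passed under each alternative tried, with adjusted p here of up to 0.00731. In 5510 genes (43.4%) the 3 KO arrays lay all above or all below the 3 WT arrays, where chance gives 10%. Leaving out KO replicate 1, 2 or 3 gave 1057, 1161 and 957 genes, leaving out WT replicate 2 or 3 gave 959 and 948, and settings that use the mixed arrays or array weights gave 2856 to 5255. With cyclic loess scaling the median difference of all genes moved from 0.12 to -0.02, and 396 genes were higher and 1275 lower (76.3% lower, against 53.7%). The balance turned to rises with all 6 arrays (38.9% lower), preparation as a block (38.8%), the mixed arrays alone (41.8%), array weights (42.5%), least squares (43.1%) and without WT replicate 1 (47.5%).

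Genes of the lists of spermatid chromatin moved in part. Of 4 measured genes on the list of transition proteins and protamines, 2 fell: Prm3 (-1.37, SE 0.25) and Tnp2 (-0.82, SE 0.19). Prm3 is on this list by its symbol, and a part of it in replacing histones is not shown here. Adjusted over the list alone, 3 fell. The values of Tnp1 (-0.48, adjusted p = 0.0790) and Prm1 (-0.15) did not pass. Both genes read high on the array scale (14.2 and 14.9 in KO, 14.6 and 15.1 in WT), where changes may be compressed. The list was lower by -0.71 on average, -0.82 relative to the median of all genes, with an adjusted p = 0.0308 in the set test. That call was lost (adjusted p = 0.779 with an estimated correlation). Of 13 testis histone variants, 3 fell, all specific to spermatids: H2al2a (-1.83, SE 0.22), H2al1m (-1.26, SE 0.21) and H2bl1 (-0.97, SE 0.23). The list alone gave 1 rise and 3 falls, and its mean (-0.17) and median (0.19) differ in sign, so the list as a whole has no single direction. Of 11 core and linker histones 1 fell, H3c7 (-0.87), which adjusted over the list alone did not pass.

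Among 21 histone acetyltransferases and deacetylases 4 rose and 2 fell, and adjusted over the list alone 7 rose and 2 fell. The deacetylase gene Hdac4 fell (-2.51, SE 0.23), while the sirtuin gene Sirt7 (1.09, SE 0.22), Hdac2 (0.75) and the acetyltransferase gene Hat1 (0.73, lost with cyclic loess scaling) rose. Of the 6 measured genes of Nut and its partners only Nutm1 fell, also when adjusted over the list alone, and Ep300, which encodes p300, differed by 0.24 (adjusted p = 0.344). Among 21 genes of chromatin remodelling in spermatids 2 rose and 1 fell, and adjusted over the list alone 4 rose and 1 fell. Cbx3, the gene of a heterochromatin protein, rose (1.61, SE 0.19), although its other probe did not pass, and the kinase gene Camk4 fell (-1.20, SE 0.32). None of these 3 lists was called by the set test (adjusted p = 0.233, 0.779 and 0.583).

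**Figure D2:**
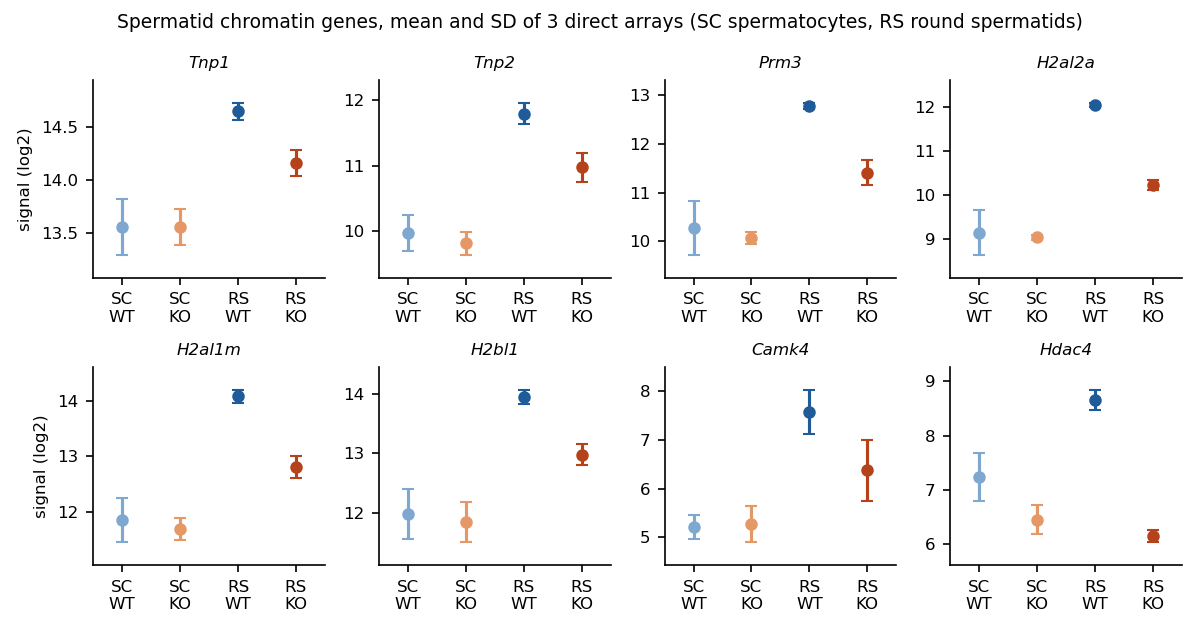
Signal (log2, vertical axes) of 8 genes in the 4 groups (horizontal axes; SC spermatocytes, RS round spermatids), each point the mean and each bar the SD of 3 direct arrays. Prm3, H2al2a and Hdac4 were lower in KO than in WT round spermatids by -1.37, -1.83 and -2.51.

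Of the other spermatid lists few members passed. Of 26 sperm tail genes 1 rose and none fell, of 24 acrosome genes 1 fell, and of 27 axoneme genes 1 fell. That was Tppp2 (-2.0, SE 0.41), which encodes a tubulin-binding protein. The mean of the axoneme list went the other way, higher on each KO array (11.08 to 11.17) than on each WT array (10.88 to 11.01). The reference genes lay apart in this way as well. Adjusted over the list alone 0 sperm tail, 0 acrosome and 1 axoneme gene passed. With cyclic loess scaling 4 sperm tail genes fell and none rose. The sperm tail list read 12.40 to 12.62 on the KO and 12.76 to 12.86 on the WT arrays, high on the array scale. Changes of such bright genes may be compressed, so a gene that did not pass is not shown to be unchanged. Of 20 regulators of spermatid transcription 1 rose (Tcfl5, 0.63) and 1 fell (Camk4), and the same number passed over the list alone. Of 20 piRNA and germ granule genes 2 rose, 0 over the list alone and 0 with cyclic loess scaling. Among 22 sex-linked spermatid genes 2 rose and 5 fell, and adjusted over the list alone 6 rose and 6 fell. Ott (-1.01, SE 0.23) and Actrt1 (-1.09, SE 0.29), both on the X chromosome, fell, and with cyclic loess scaling 7 fell and none rose.

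Some meiotic and mitotic division genes rose in KO round spermatids. Of 25 measured, 6 rose and none fell, and 8 rose when adjusted over the list alone. Examples are Kif11, a spindle motor (1.02, SE 0.21), Mcm5, of the replicative helicase (1.12, SE 0.26), and Top2a, a topoisomerase (0.72). The list was higher by 0.53 on average (0.41 relative to the median of all genes, adjusted p = 0.0262), a call that was lost (adjusted p = 0.772 with an estimated correlation). With cyclic loess scaling 2 of its genes rose. None of 26 meiotic prophase genes passed on either count. The mean of that list was higher by 0.26, with each KO array (10.01 to 10.14) above each WT array (9.65 to 9.97), but the set test did not call it (adjusted p = 0.268). The reference genes lay apart in the same direction (10.14 to 10.41 in KO, 9.85 to 10.11 in WT), so this separation is not particular to prophase genes. In addition, 1 of 13 spermatogonial genes rose (Elavl2, 1.01, which did not pass over the list alone or with cyclic loess scaling).

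Stress and housekeeping lists had few members that passed. Of 16 genes of the unfolded protein response 3 rose, 7 over the list alone, among them Xbp1 (0.93, SE 0.18) and Atf4 (0.81, SE 0.15), whose other probe has the opposite sign. Fry tests whether the genes of a list move on balance in one direction, without comparing them with other genes. There this list had an adjusted p = 0.00138 and was 1 of 6 called. The others were axoneme, division and p53 genes, higher on average, and transition protein and protamine and erythroid genes, lower on average. The set test against other genes did not call the unfolded protein response list (adjusted p = 0.0582). Of 17 p53 and cell death genes 4 rose and 1 fell, and over the list alone 8 rose and 2 fell. Bcl2l11, which encodes Bim, fell (-1.89, SE 0.26), and Apaf1 rose (0.96, SE 0.24). With cyclic loess scaling the 4 rises did not pass. Hspa8 (0.98, SE 0.23) was the 1 of 15 heat shock and immediate early genes that rose, with 7 rises and 1 fall over the list alone. That list was higher by 0.59 on average, and its mean on each KO array (9.22 to 9.51) lay above that on each WT array (8.61 to 8.89), but the set test did not call it (adjusted p = 0.123). Its members Fos (1.53, adjusted p = 0.0686), Junb (1.55, adjusted p = 0.0701, not detected on any WT array) and Egr1 (1.17, adjusted p = 0.0795) did not pass. Replicate 2 read lowest of the direct arrays of its group both in this list and in the macrophage list (9.22 and 7.32 in KO, 8.61 and 6.69 in WT). Whether other cells in the fractions account for the higher mean of this list was not tested. Of 26 proteasome genes 3 rose, 0 over the list alone and 0 with cyclic loess scaling. Of 25 oxidative phosphorylation genes 3 rose, also over the list alone, but with cyclic loess scaling 1 rose and 2 fell. Atp5b (0.64, SE 0.13) passed under every alternative. Of 26 ribosomal protein genes 1 rose and 1 fell, 0 over the list alone, and with cyclic loess scaling 7 fell. Of 14 testis glycolysis genes 2 rose on both counts, and 0 with cyclic loess scaling. Of 14 reference genes 1 rose on both counts, the transferrin receptor gene Tfrc (1.21, SE 0.18). The mean of the reference list, too, was higher on each KO array (10.14 to 10.41) than on each WT array (9.85 to 10.11). Such separation of list means is thus not particular to heat shock genes. None of 10 interferon response genes passed.

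The fractions also hold RNA of other testis cells, and few of their marker genes passed. Macrophage and immune genes were higher by 0.85 on average (adjusted p = 0.0308; adjusted p = 0.817 with an estimated correlation), although the list means of the KO arrays (7.32 to 8.66) overlap those of the WT arrays (6.69 to 7.56). Of 17 measured, 1 rose, H2-Aa (1.16, at least 1.55-fold), also over the list alone. The 4 measured erythroid genes were lower by -0.91 on average (adjusted p = 0.0308; adjusted p = 0.554 with an estimated correlation). None passed over all genes, and 4 fell when adjusted over the list alone. Of 15 Sertoli cell genes 3 fell, among them the cystatin genes Cst12 (-1.22, SE 0.29) and Cst9 (-1.38, SE 0.33), and over the list alone 1 rose and 3 fell. Vwf fell (-1.25, SE 0.26) as the 1 of 13 peritubular and endothelial genes that passed on either count, and none of 6 Leydig cell genes did. The means and medians of the lists of Nut partners, testis histone variants, acrosome and regulators of spermatid transcription differ in sign, and none of these lists was called.

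**Figure D3:**
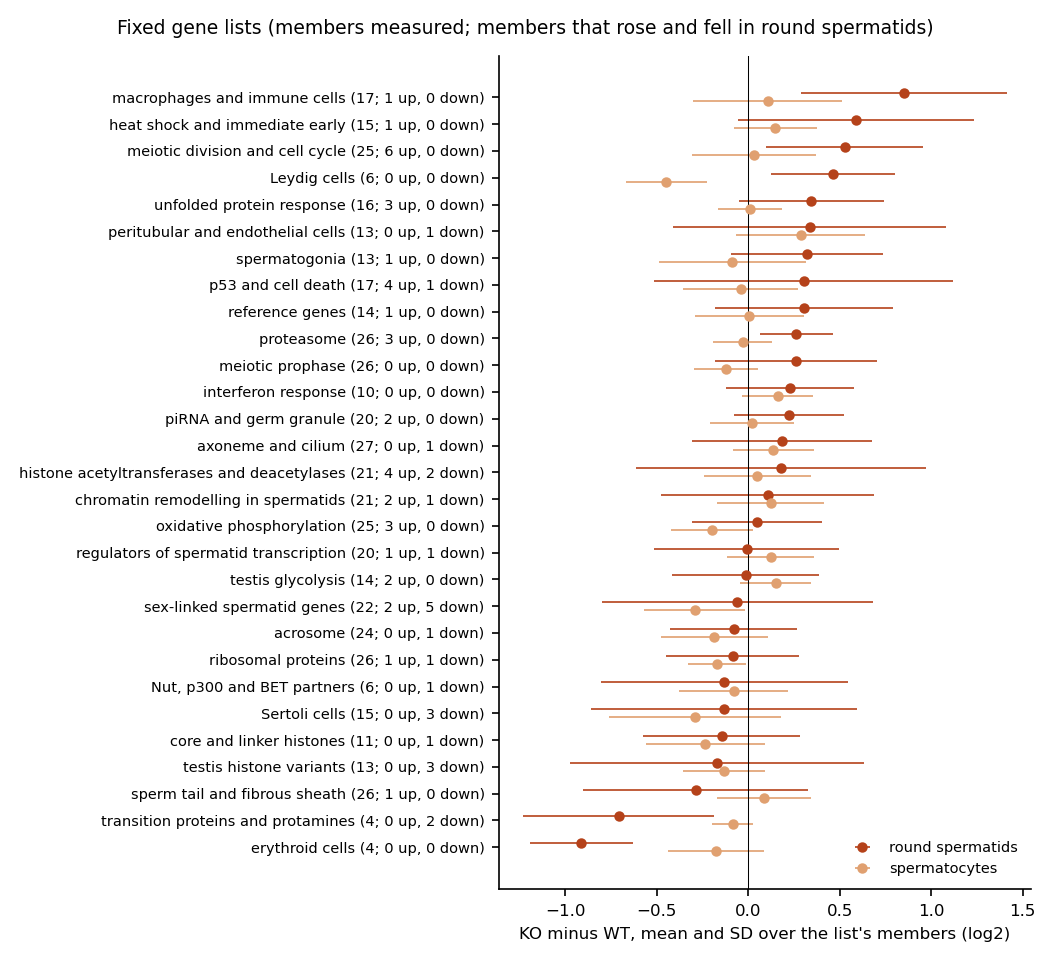
Mean KO minus WT difference (log2, horizontal axis) of each of 29 fixed gene lists (vertical axis) in round spermatids and spermatocytes, with bars for the SD over the measured members. Macrophage genes (0.85) and erythroid genes (-0.91) lie at the ends in round spermatids, and with cyclic loess scaling the mean of oxidative phosphorylation genes changes from 0.05 to -0.12.

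Whether falls in round spermatids were more frequent among X-linked genes depended on the setting. Of 311 X-linked genes 39 (12.5%) fell, against 665 of 9712 autosomal genes (6.85%; odds ratio 1.95, 2-sided Fisher's exact p = 4.02e-04). With cyclic loess scaling the odds ratio was 1.67 (Fisher's exact p = 0.00441), but the call ended without KO replicate 1 or 3 or WT replicate 1 or 2 (odds ratios 1.30, 1.41, 1.26 and 1.54). It also ended without a detection filter (1.18, Fisher's exact p = 0.365) and with least squares (1.43, Fisher's exact p = 0.0621). Rises were not more frequent there (odds ratio 0.906, Fisher's exact p = 0.742). Across genes, which are not independent replicates, the KO against WT difference correlated with the stage difference, taken as the mean of both genotypes, at r = -0.40 (Spearman's rho -0.41). The 9 other splits of the 6 round spermatid arrays gave r of up to 0.48 in size, so no direction is read from it.

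The same comparison in spermatocytes asks what changes before the haploid stage. Fewer genes changed, and most were among the falls and rises of round spermatids. Bpifa3 fell by 5.11 (SE 0.42, at least 17.5-fold), and Dydc2 (-5.02, SE 0.24, at least 17.9-fold), Cstl1 (-4.33, SE 0.23) and Car2 (-3.81, SE 0.40) fell as well. Cnga3 rose by 3.05 (SE 0.34, at least 5.07-fold) and Tspan17 by 2.16 (SE 0.24), with Bmp7, the gene of a bone morphogenetic protein, higher by 2.69 (SE 0.32). In total 106 genes changed, 24 higher and 82 lower, of which 16 and 68 have a symbol. The model uses 1 spread per gene for all groups, although it can differ between them. For Bpifa3 the SD was 0.04 in WT round spermatids and 1.17 in WT spermatocytes. With the KO and WT spermatocyte groups fitted alone, 35 genes passed. In 1169 genes (9.20%) the arrays of the groups lay apart, where chance gives 10%.

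The other 6 of the 10 largest falls in spermatocytes were Lelp1 (-4.02), Glt6d1 (-4.01, at least 10.05-fold), Odf3b (-3.45), the transcription factor gene Etv2 (-3.40, at least 6.80-fold), the calcium-binding protein gene Scgn (-3.33, at least 8.03-fold) and Tmco5b (-3.01). The other 7 of the 10 largest rises were C1qtnf12 (1.99), Lrrc3 (1.93, at least 2.11-fold), B4galt5 (1.93, at least 2.54-fold), Mtmr3 (1.89), the phosphatase gene Inpp4a (1.46), Insig1 (1.19) and Lrrk1 (1.17, at least 1.26-fold). The last 3 and C1qtnf12 lost their calls under some alternatives, and the other probe of Inpp4a did not pass. Markers of other cells differed within the KO group: replicate 1 read 7.56 in the Sertoli cell list and 6.60 in the macrophage list, against at most 6.66 and 5.57 on the other arrays of that group. Leaving out KO replicate 2 or 3 gave 68 and 60 genes, while the authors' processed values gave 51 genes and settings that use the mixed arrays gave 1282 to 5985.

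Of the list members only Cbx3 passed in spermatocytes (1.17, SE 0.19, adjusted p = 0.0103), and its other probe has the opposite sign. The call ended when only the 2 groups were fitted. The set test called 4 lists, each with small mean differences. Axoneme genes were higher by 0.14 on average (27 measured, adjusted p = 0.0118; adjusted p = 0.776 with an estimated correlation). Sex-linked spermatid genes (22 measured, -0.29, adjusted p = 0.00919), oxidative phosphorylation genes (25 measured, -0.20, adjusted p = 0.0169) and ribosomal protein genes (26 measured, -0.17, adjusted p = 0.0118) were lower. These 3 calls were lost too (adjusted p = 0.835 each with an estimated correlation), and fry called none of the 29 lists. Adjusted over the list alone, 1 sex-linked gene fell, 1 Sertoli cell gene fell and Cbx3 rose, and 0 members of the other lists passed. Transition protein and protamine genes differed by -0.09 on average, and the sign of that mean turned with cyclic loess scaling. Leydig cell genes differed by -0.45 on average (6 measured, none passed), with KO arrays that read 12.26, 7.63 and 9.62. This difference was -1.66 without KO replicate 1 and 0.66 without KO replicate 2. X-linked genes were no more frequent among the falls (1 of 311, odds ratio 0.471, Fisher's exact p = 0.725), and 0 were among the rises.

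Genes changed in spermatocytes overlapped those changed in round spermatids. Of the 82 falls in spermatocytes 78 were also falls in round spermatids, where 6.55 would be shared by independence, and of the 24 rises 21 were shared (1.65 by independence). None changed in opposite directions. Across genes the KO against WT differences of both stages correlated at r = 0.60 (Spearman's rho 0.37). Both stages come from the same fractionations, which independence ignores. The 9 other splits of the 6 fractionations into 3 and 3, applied to both stages together, gave r of -0.01 to 0.44 (Spearman's rho of up to 0.32). They changed 0 genes in round spermatids and at most 1 in spermatocytes, so they say nothing on the number shared. The plot of both differences shows each gene.

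**Figure D4:**
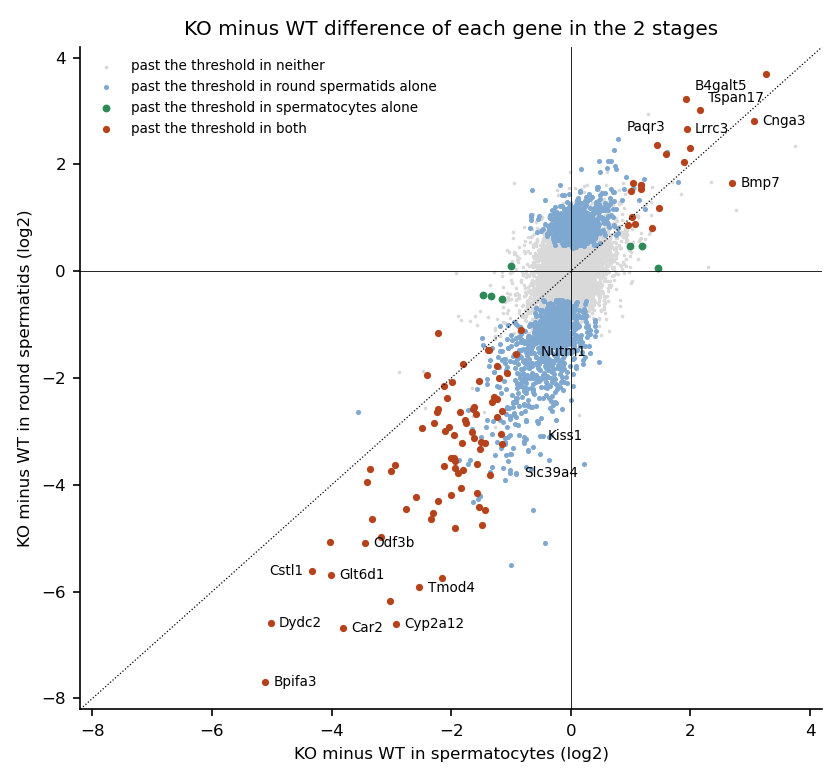
KO minus WT difference of each gene in spermatocytes (log2, horizontal axis) and in round spermatids (log2, vertical axis), coloured by the stages in which it passed the threshold, with a dotted line of equal differences. Bpifa3, Dydc2 and Car2 lie at the lower left, with -7.68, -6.58 and -6.67 in round spermatids and -5.11, -5.02 and -3.81 in spermatocytes.

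The difference of the differences tests directly whether the effect of genotype depends on the stage. The zinc transporter gene Slc39a4 (-2.86, SE 0.27), Kiss1, which encodes kisspeptin (-2.57, SE 0.25), Cyp2a12 (-3.68, SE 0.36), Tmem255b (-2.21, SE 0.26) and Gsdmd, of the pore-forming gasdermins (-2.77, SE 0.33), had the smallest adjusted p (9.58e-04 to 0.00269). Several of these values rest on the background level. No array of KO round spermatids or of either spermatocyte group detected Kiss1 or Tmem255b, so a fall in spermatocytes could not have been seen, and no KO array of either stage detected Cyp2a12, so its value mostly restates its rise of 3.59 from WT spermatocytes to WT round spermatids. Slc39a4 and Gsdmd were detected on 1 of 3 KO spermatocyte arrays. Among list members Hdac4 (-1.72, SE 0.32) and H2al2a (-1.73, SE 0.31) fell more in round spermatids. Rhox13, Gadd45b, Atf4 and Tfrc (1.70, 1.31, 1.07 and 1.23) moved the other way, and these 6 calls were lost under some alternatives. In total 189 genes passed, 23 with a higher and 166 with a lower KO against WT difference in round spermatids (87.8% lower). This direction turned with all 6 arrays (41.8%), the mixed arrays alone (38.2%) and preparation as a block (39.5%), and array weights gave 54.7%. Fry called 1 list, the unfolded protein response (adjusted p = 0.0210). The set test called 8 of 29 lists, and none of these calls held with an estimated correlation (adjusted p = 0.698 for the erythroid and unfolded protein response lists and adjusted p = 0.894 for the others). In 9 of 100 splits of the genotypes within each stage as many genes passed, but each of the other 8 keeps the genotypes of round spermatids together, so these splits leave open whether chance gives such a count. Leaving out 1 array gave 82 (without WT spermatocyte replicate 2) to 490 genes (without WT spermatocyte replicate 3).

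The comparison of round spermatids with spermatocytes in WT mice gives the difference between the fractions. Development of germ cells and the content of other testis cells both enter it, and they were not told apart. Most genes of the sperm tail and the acrosome and most sex-linked spermatid genes rose in round spermatids, and Leydig cell genes fell. Ropn1, of the fibrous sheath, rose by 3.58 (SE 0.30), Zp3r, of the acrosome, by 2.84 (SE 0.39) and Nutm1 by 2.09 (SE 0.24). Piwil1, a piRNA-binding protein of meiotic cells, fell by 3.04 (SE 0.18), and so did Cyp17a1, a steroidogenic enzyme of Leydig cells (-5.32, SE 1.15). The 5 largest rises were Tspan6 (3.80, whose other probe has the opposite sign), the globin gene Hba-a1 (3.69), Cyp2a12 (3.59), Ropn1 and Tctex1d1 (3.56), and the 5 largest falls were Cyp17a1, Klk1b21 (-5.22), Klk1b27 (-5.18), Klk1b24 (-4.99) and Ephx1 (-4.59). Which Klk1b paralog each probe reads is uncertain here too.

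In WT mice 7657 genes differed, 3604 higher and 4053 lower in round spermatids. In 8603 genes (67.7%) the arrays lay apart, against 10% by chance. Of 26 sperm tail genes 23 rose (adjusted p = 7.98e-06), of 24 acrosome genes 14 rose and 1 fell (adjusted p = 0.00177), of 4 transition protein and protamine genes 3 rose (adjusted p = 0.0209), of 22 sex-linked genes 15 rose (adjusted p = 9.66e-05) and of 20 regulators of spermatid transcription 15 rose and 2 fell (adjusted p = 0.00165). These 5 calls were lost (adjusted p = 0.598 each with an estimated correlation). Most members of these lists rose all the same, so the loss does not weigh one list against another. The same numbers passed over these lists alone, with 1 more fall among the regulators. Of 20 piRNA genes 3 rose and 13 fell (adjusted p = 0.0208), among them Tdrd5 (-3.32), and of 26 proteasome genes 14 fell (adjusted p = 0.00819; 13 over the list alone), and both calls were lost (adjusted p = 0.598 each with an estimated correlation). Of 26 meiotic prophase genes 3 rose and 11 fell, and of 25 division genes 2 rose and 11 fell, without a call. Histone genes went both ways: H2al2a (2.92) and H2al1m (2.22) rose and H3f3b (-2.66) fell. All 6 Leydig cell genes fell, while 11 of 17 macrophage genes (C1qb, 2.97; adjusted p = 0.00457), 4 of 4 erythroid genes (Hbb-bs, 3.34; adjusted p = 0.00819) and 8 of 15 Sertoli cell genes (Cst12, 1.81; adjusted p = 0.0208) rose. These 3 calls were lost as well (adjusted p = 0.598 each with an estimated correlation). Fry called 21 lists, among them those of meiotic prophase (adjusted p = 0.00371) and division genes (adjusted p = 0.00467). With cyclic loess scaling the median difference of all genes moved from -0.12 to 0.09, and the share of falls from 52.9% to 42.4%.

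The same comparison in KO mice asks how much of this difference between the fractions is also seen there. Most sperm tail, acrosome and sex-linked spermatid genes rose here as well, such as Ropn1 by 2.89 (SE 0.30), Zp3r by 2.89 (SE 0.39) and Sly, a Y-linked spermatid gene, by 2.54 (SE 0.25). Prm3 (1.34, SE 0.25), Tnp2 (1.16, SE 0.19) and H2al2a (1.19, SE 0.22) rose, and Piwil1 fell by 2.72 (SE 0.18). Of these, only for H2al2a did the difference between stages itself differ between the genotypes past the threshold (adjusted p = 0.0184). Nutm1 rose by 1.24 (SE 0.24). The 5 largest rises were Dcn (4.11), Cd74 (3.51), Laptm5 (3.17), C1qc (3.16) and Fcrls (3.11), which include genes of stroma and macrophages. The 5 largest falls were Septin12 (-4.73), Klk1b27 (-4.55), Klk1b21 (-4.51), Klk1b24 (-4.01) and Cyp17a1 (-3.98).

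In KO mice 6399 genes differed, 3351 higher and 3048 lower in round spermatids, and in 7354 (57.9%) the arrays lay apart. Of 26 sperm tail genes 19 rose (21 over the list alone, adjusted p = 3.61e-05), of 24 acrosome genes 16 rose and 1 fell (18 and 1 over the list alone, adjusted p = 6.25e-05), of 22 sex-linked genes 21 rose on both counts (adjusted p = 2.76e-08) and of 20 regulators of spermatid transcription 16 rose and 1 fell (16 and 2 over the list alone, adjusted p = 4.62e-04). These 4 calls were lost (adjusted p = 0.63 each with an estimated correlation). Macrophage genes rose in 15 of 17 (17 over the list alone, adjusted p = 1.40e-05) and Sertoli cell genes in 10 of 15 (adjusted p = 0.00585). These 2 calls were lost as well (adjusted p = 0.63 each with an estimated correlation), and fry called 15 lists. Of 25 division genes 4 rose and 4 fell, among them Kif11 (-1.14, SE 0.21). Erythroid genes rose in 3 of 4, and Leydig cell genes fell in 4 of 6 (5 over the list alone), neither with a call of the set test. The plot of cell type lists gives their levels on every array.

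**Figure D5:**
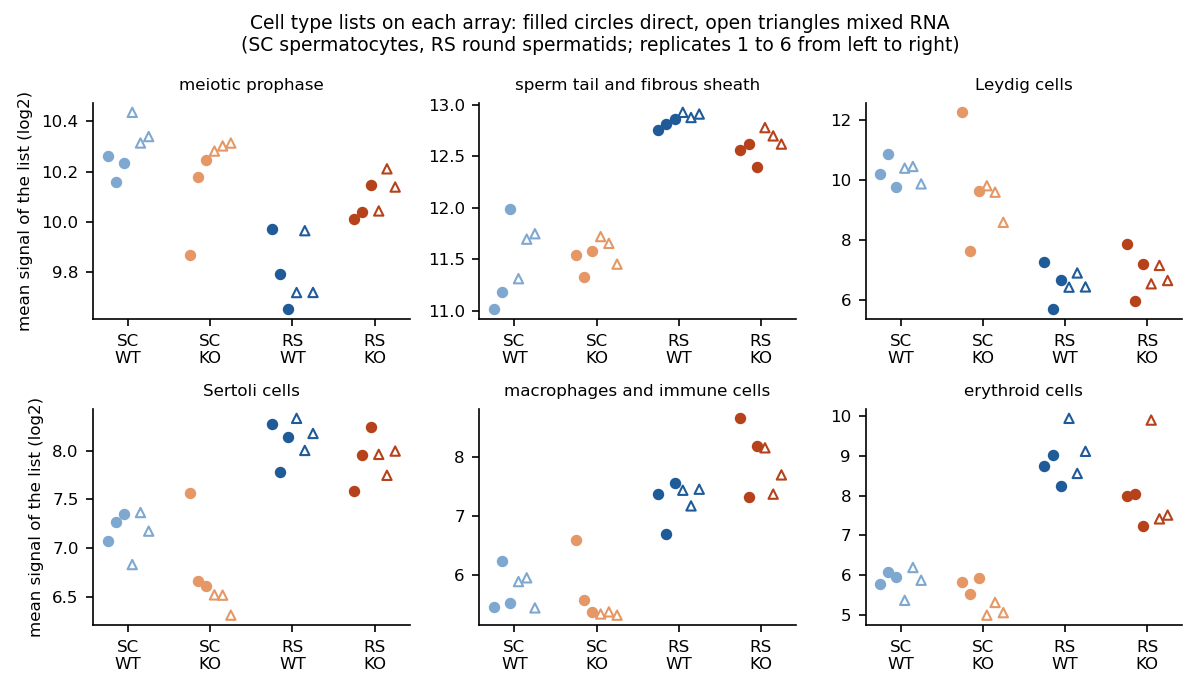
Mean signal (log2, vertical axes) of 6 cell type lists on each of the 24 arrays by group (horizontal axes; SC spermatocytes, RS round spermatids), with filled circles for direct and open triangles for mixed arrays. In KO spermatocytes the direct array of replicate 1 reads 7.56 in the Sertoli cell list and 6.60 in the macrophage list, above the other arrays of its group.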

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

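In this part, the tests of fewer spermatids, other mixing proportions, RNA of another group, late spermatids, a passenger segment and a strain variant, and the sorting of splits by the genotypes they keep together, were chosen only after the result was seen, and the others were chosen before the data were examined.

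Genes lower in KO spermatocyte fractions were mostly lower in KO round spermatids too. Round spermatid RNA carried over into the spermatocyte fractions may account for this. The 82 falls were higher in WT round spermatids than in WT spermatocytes by a median of 2.29, which reaches the upper quartile of 28 spermatid list members (2.23, SE of the median 0.134), and 76 of them passed. The spermatid lists did not fall with these genes. They differed by a median of -0.055 there (SD 0.32), against -1.91 for the falls, or -1.51 with the 43 of them not detected on any KO array at their bounds. Prm3 and Tnp2 of these lists read 10.28 and 9.97 in WT spermatocytes, so the lists may not follow the content of spermatids alone. Whether the KO spermatocyte fractions hold fewer spermatids therefore stays open. An effect of genotype in spermatocytes themselves stays open and was not tested apart from carry-over.

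The mixed arrays of KO spermatocytes lie apart from the direct arrays of the group, a signal in samples that the comparisons do not use. On 7.39% of 8016 genes all 3 mixed arrays lay more than log2 0.50 outside the range of the direct arrays, against at most 1.67% in the other groups. Mixing in any proportions keeps levels within that range, so other proportions than stated are argued against as the only source. Together with another source they stay open. Arrays made mainly of RNA of another group are argued against too. Of the 3 mixed arrays 0 lay nearest to another group's direct mean (distances up to 0.649 to their own group and at least 0.790 to others). A smaller admixture could leave an array nearest to its own group, so it stays open. A batch of arrays for the mixed samples cannot be told apart from another source, because the shift correlated with that of the other groups at a median of 0.37 (0.37, 0.14 and 0.43), between the bounds set before. No biological explanation was tested.

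The 98 falls in KO round spermatids with a fitted difference of at least 8-fold had a median of -3.67, or -3.50 with the 41 of them not detected on any KO array at their bounds. Transition protein, protamine and sperm tail genes differed by a median of -0.37 (12 members, SD 0.829), so they did not fall as these genes did. The brightest members in WT round spermatids, Tnp1 and Prm1 among them, were left out. Prm3 and Tnp2 already read 10.28 and 9.97 in WT spermatocytes, so these genes do not mark late spermatids alone. Whether the KO fractions hold fewer late spermatids therefore stays open. A passenger segment of the strain of origin around Nutm1 is argued against, since 1.45% of the 69 falls with a known place (1 gene) are among the 200 genes nearest to it. For 18 of the 19 genes that have another kept probe, the other probes were all lower past the threshold. This argues against a strain variant under the probe only where the probes of a gene read separate stretches. Probe sequences were not available, so this could not be checked. Of the 20 other probes of the 19 genes, 19 (95%) were lower past the threshold, but the only other probe of Kif1a was not (0.27, adjusted p = 0.715). The other 79 falls have no such probe, so for them and for Kif1a a strain variant stays open. For those 18 genes an effect of genotype on the transcripts may be put as a hypothesis, found and tested on the same data. A strain variant under all probes of a gene and fewer late spermatids are still open for them. Other technical explanations, such as strain differences elsewhere in the genome, were not tested.

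The 6 direct arrays of each pair of groups allow 10 splits, too few for a share under 0.05. In each case 1 split, the real one, gave as many genes: 1890 in round spermatids (highest other 0), 106 in spermatocytes (highest other 1), 7657 between stages in WT (highest other 0) and 6399 in KO (highest other 0). For the difference between stages 9 of 100 splits of the genotypes within each stage gave at least the 189 genes found, and the highest other gave 1418. All 8 of the other splits with as many genes keep the genotypes of round spermatids together, and so carry the effect of genotype there into the difference, while the 85 that mix the genotypes in both stages gave 0 genes. Such splits do not decide whether chance gives the count.

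The effect of genotype differed between stages, by the test of the difference itself, in these genes named in the text: Slc39a4 (-2.86), Kiss1 (-2.57), Cyp2a12 (-3.68), Tmem255b (-2.21), Gsdmd (-2.77), Klk1b9 (-3.59), Tmod4 (-3.39), Car2 (-2.86), Dydc2 (-1.56), H2al2a (-1.73), Hdac4 (-1.72) and Defb33 (-1.76), with a lower value in round spermatids, and Paqr3 (1.68), Rhox13 (1.70), Atf4 (1.07), Tfrc (1.23) and Gadd45b (1.31), with a higher one. Background sets part of these values: no KO round spermatid array detected Kiss1, Tmem255b, Cyp2a12, Klk1b9 or Tmod4, no spermatocyte array detected Kiss1 or Tmem255b, no KO spermatocyte array detected Dydc2, Cyp2a12 or Tmod4, and no WT round spermatid array detected Gadd45b. Car2, Slc39a4, Gsdmd and Klk1b9 were detected on 1 of 3 KO spermatocyte arrays. For these genes the size of the difference between stages is not bounded.

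Single arrays lay far from the other 5 of their group in 5 of 48 tests, where chance gives about 1 in 20 (2.40 of 48) for independent samples. Replicates 4 to 6 are mixtures of replicates 1 to 3, so that rate does not hold strictly here. Replicate 1 of KO spermatocytes had low meiotic prophase genes (9.87, nearest 10.18) and high Sertoli cell (7.56, nearest 6.66) and macrophage genes (6.60, nearest 5.57). Replicate 4 of KO round spermatids, a mixed array, had high erythroid genes (9.90, nearest 8.04), and replicate 1 of that group had low acrosome genes (11.48, nearest 11.73).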

How the results depend on the processing

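The fits with preparation as a block and with a replicate block within genotype were chosen after seeing the data, and the other alternatives before the data were examined. Over 29 settings, named genes that passed kept their side of the threshold in 4126 comparisons with an alternative and lost it in 377, those that had not passed came to pass in 159, and none that passed in either setting had the opposite direction. Means of lists that were not called did change sign with cyclic loess, such as oxidative phosphorylation in round spermatids. Lists that were called kept their call in 342 and lost it in 122, and those not called were called in 100. The cause was not tested for any change below. A slide block was not run, since the slides are not given.

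Quantile normalization without background correction gave 51 genes in spermatocytes and 337 for the difference between stages, as did the authors' processed values (51 and 337). All 6 arrays as replicates, which counts each RNA more than once, gave 4912 genes in round spermatids, 3528 in spermatocytes and 2136 for the difference, least squares 2856, 1282 and 429, the mixed arrays alone 4054, 5985 and 3058, and preparation as a block 5255, 3932 and 2500. Array weights gave 3777 in round spermatids and 1123 for the difference, and only the groups compared 35 in spermatocytes. Nutm1 in spermatocytes passed with all 6 arrays (-0.54, adjusted p = 0.0169) and with preparation as a block (-0.54, adjusted p = 0.0158).

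With an estimated correlation 0 lists were called in round spermatids, 0 in spermatocytes, 0 for the difference between stages, 0 in WT and 0 in KO. This held even between stages, where most sperm tail genes rose, so that setting does not tell lists apart. Without a detection filter 13, 7, 20 and 15 lists were called in round spermatids, spermatocytes, WT and KO. All 6 arrays gave 0 and 7 in round spermatids and spermatocytes, and least squares 1 and 7.

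For X-linked genes the odds ratio without a filter was 0.526 for rises and 1.18 for falls in round spermatids (Fisher's exact p = 0.00982 and 0.365). With all 6 arrays it was 0.132 for rises and reversed to 1.60 for falls in spermatocytes (Fisher's exact p = 7.65e-12 and 0.00152). Least squares gave 1.43 for falls in round spermatids and 0.173 for rises in spermatocytes (Fisher's exact p = 0.0621 and 8.08e-05).

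Leaving out 1 array gave 948 to 2115 genes in round spermatids, 60 to 105 in spermatocytes, 82 to 490 for the difference between stages, 6652 to 7525 in WT and 5208 to 6607 in KO. For the difference it was 98, 106 and 83 without KO round spermatid replicate 1, 2 and 3, 109 and 89 without WT round spermatid replicate 2 and 3, 103 and 111 without KO spermatocyte replicate 2 and 3, and 82 and 490 without WT spermatocyte replicate 2 and 3. Called lists ranged from 1 to 5, 0 to 7, 0 to 9, 10 to 11 and 6 to 10. Nutm1 ranged from -1.60 to -1.43 in round spermatids and from -0.90 to -0.34 in spermatocytes, and the odds ratio of X-linked falls in round spermatids from 1.26 to 1.93. The correlation with the stage difference in spermatocytes ranged from -0.25 to 0.16, the latter without WT spermatocyte replicate 3.

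Cyclic loess gave 396 rises and 1275 falls in round spermatids (76.3% falls, against 53.7%), 3 and 151 for the difference between stages (98.1% against 87.8%) and 4303 and 3164 between stages in WT (42.4% against 52.9%), and 28 calls of named genes were lost. Other settings gave lower shares: use of the mixed arrays or array weights gave 38.8% to 43.1% falls in round spermatids, 50.9% to 67.2% in spermatocytes and 38.2% to 65.0% for the difference between stages. For the difference between stages a replicate block across all 4 groups gave 153 genes (94.1% falls). A block within genotype gave 204 (97.1%) and a random block 269 (82.2%). None of these blocks moved this count by more than 1.5 times, but preparation as a block, which adds the mixed arrays, moved it further. The authors' values gave 64.7% falls in spermatocytes, against 77.4%, and 77.7% for the difference. Signals near the background limit what can be called, since 38.4% of probes passed the detection filter.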

Other observations

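The families below were chosen after their values were seen. Grouping named genes by the stem of their symbol gave 312 families of at least 5 measured members. Beta-defensin genes, several of which are known for expression in the male reproductive tract, were the 1 family past the threshold: 6 of 10 fell in KO round spermatids (60%, against 6.61% of the 9555 named genes without clone and locus names; Fisher's exact p = 1.37e-05, adjusted p = 0.00852 over 624 tests). Among them are Defb33 (-3.69, SE 0.26), Defb11 (-2.34, SE 0.57), Defb30 (-1.68, SE 0.38) and Defb15 (-1.67, SE 0.35). Defb36, also among the 6, is on the Sertoli cell list as well, and whether other cells in the fractions account for part of this was not tested. Genes are not independent replicates here either. In spermatocytes Defb33 fell too (-1.93). Spermatid genes of the Cypt family fell in 4 of 6 (adjusted p = 0.0531, Fisher's exact), with Cypt1 (-0.85) and Cypt2 (-0.87), and kallikreins in 5 of 10 (adjusted p = 0.0531, Fisher's exact), without passing as families. Protein arginine methyltransferases rose in 4 of 6 (Prmt1 0.72, Prmt3 1.08, Prmt5 0.73, Prmt7 0.54), also without passing as a family (adjusted p = 0.0709, Fisher's exact), and Prmt1, Prmt3 and Prmt7 lost their calls with cyclic loess scaling.

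Other short H2A variants on the X chromosome, outside the fixed lists and chosen after their values were seen, fell in KO round spermatids: H2ap (-1.92, SE 0.26), H2al3 (-1.75, SE 0.24), H2al1n (-1.43, SE 0.21) and H2al1e (-1.17, SE 0.18). They were picked because they fell, and members of this group that did not fall were not counted. Among all genes with the symbol stem H, 12 of 73 fell, without passing as a family (adjusted p = 0.218, Fisher's exact). In spermatocytes the differences of these H2A variants were -0.81, -0.41, -0.20 and -0.16, and none passed. The H2al1 genes are alike in sequence, so which of them a probe reads is uncertain.

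On the mixed arrays Nutm1 read 7.39, 6.85 and 6.98 in KO and 8.40, 8.25 and 8.30 in WT round spermatids, and 5.30, 5.94 and 5.48 in KO and 5.65, 6.10 and 6.25 in WT spermatocytes. Mixed minus direct means of marker lists in KO spermatocytes were -0.49 for Sertoli cells, -0.51 for Leydig cells, -0.50 for macrophages and -0.64 for erythroid cells. In round spermatids the erythroid list was higher on the mixed arrays by 0.52 in KO and 0.54 in WT.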
